A study of Homo sapiens with 18 samples.

How the data were processed

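RNA was measured by sequencing in 18 libraries from HAP1, a near-haploid human cell line derived from the chronic myeloid leukaemia line KBM-7. Per the labels, 6 libraries came from the unmodified parental line and 12 from a line in which SARS2 was deleted and a transgene for SARS2 carrying 1 FLAG tag was added. Cells were grown in IMDM with 15 ng/mL doxycycline, the drug that keeps such a transgene on, until it was removed for the groups without it, per the labels' protocols. RNA was extracted with Trizol and chloroform followed by a column kit, and a university core made libraries for 151-bp paired-end sequencing on an Illumina NovaSeq, per the labels' protocols. The kind of deletion is not given in the sources used here, so RNA of the deleted locus may still have been counted, and reads of the transgene fall on the same gene name.

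The authors deposited 3 tables of raw read counts per gene, with whole numbers and no normalization, per the file headers and values. The submitters' processing notes name cutadapt 2.3, HISAT2, SAMtools, Subread, featureCounts and DESeq2, and the build GRCh38, with no role or order for each tool. The column headers of the tables carry the letters RF, which is HISAT2's name for reverse-stranded pairs. The annotation release and the strand setting used in counting are not given in the sources used here. Uncertain for that reason are counts of overlapping or antisense genes (SARS2 and its divergent neighbour MRPS12, FBXL19-AS1, NHSL1-AS1, PDE11A-AS1), of pseudogenes (PRKXP1, RPL41P5, SRSF11P1, PPIAP46), of the metallothionein family and of the ribosomal protein genes RPS10 and RPL17, which lie in readthrough loci. Each table held 59251 genes with their GRCh38 coordinates. In the tables, 16 genes were broken over several lines and were rejoined. The 6 libraries held in 2 tables were identical in both, and each was taken a single time. All columns of per-sample values were matched to samples by name. The 37 genes of the mitochondrial chromosome held 0 counts in every library, for a reason not given in the sources used here. The mitochondrially encoded messenger and transfer RNA lists, with MT-TS1 and MT-TS2 for serine, thus had no tested members. The nuclear copy MTATP6P1 of such a gene held 50370 to 120967 counts per library, of untested origin.

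Library totals ran from 66850705 to 111123481 counts, and 25062 to 27382 genes had at least 1 count. The 10 most abundant genes held 3.27% to 3.99% of each library's counts. Replicates of a group differed by more than counting noise in every pair. A chi-square per gene over genes with at least 20 counts summed over both libraries was 4.97 to 95.6, so no library was treated as a copy of another. Spearman's rho between replicates, across genes, was 0.987 to 0.995. The coefficient of variation from the common dispersion was 0.12.

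Counts were tested with edgeR 4.0.16 in R 4.3.3. Low genes were removed with filterByExpr by group, leaving 21615 genes, and libraries were scaled with TMM. A quasi-likelihood model with 1 mean per group was fitted to all 18 libraries, so that all groups shared an estimate of the spread. The 10 comparisons were each day without doxycycline against doxycycline in the deleted line (days 3, 6 and 9), day 6 against day 3, day 9 against day 6, no doxycycline against doxycycline in the parental line, the deleted line against the parental line with doxycycline, and, for each day, the deleted line's change minus the parental line's change. P-values were adjusted with the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Levels are CPM, counts relative to the TMM-scaled library size, computed here from the deposited counts and given as mean ± SD with n = 3; standard errors (SE) are those of the log2 fold change. No statement in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

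A set of 34 gene lists was fixed before the data were examined: targets of the stress transcription factor ATF4, the unfolded protein response of the endoplasmic reticulum, heat shock, antioxidant targets of NRF2, targets of p53, interferon response, NF-kB targets, hypoxia targets of HIF and metallothioneins. It also held ribosome biogenesis genes driven by MYC, cytosolic ribosome, mitochondrial ribosome, nuclear genes of respiratory complex I and of complexes II to V, mitochondrial chaperones and proteases, factors for mitochondrial DNA maintenance, transcription and translation, mitochondrial and cytosolic transfer RNA synthetases, and mitochondrially encoded messenger and transfer RNAs. The others covered the tricarboxylic acid cycle, glycolysis, serine, glycine, one-carbon and proline synthesis, nucleotide synthesis, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, lysosome and autophagy, DNA replication, mitosis, replication-dependent histones, and markers of haematopoietic, epithelial and mesenchymal cells. The 32 lists with at least 4 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. For each list described, the members passing the test over all genes are given beside the count adjusted over the list alone.

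Genes named by rank passed the test, had a gene symbol, a mean of at least 5 CPM in the higher group and no overlap of CPM between the 3 libraries of each group. They were the 10 highest and 10 lowest log2 fold changes for day 9 and for the comparison of lines, or the 5 highest and 5 lowest for other pairs of groups. For the differences between lines they were the 5 of each sign with the smallest p. Up to 4 members with the smallest p of each list described, and members that passed the test against the direction of most, are named as well. SARS2, tested genes within 20 kb of it, ATF4, ATF5 and DDIT3 are named regardless of their values. The nuclear RNAs NEAT1 and MALAT1 were chosen after their values were seen. The condition of a gene symbol was read, after the data were examined, as leaving out LOC identifiers; 18 were passed over for the 120 places. Results of a few genes that the rule names are not reported here.

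The following alternatives were computed: DESeq2 1.42.0 (Wald test), limma-voom, DESeq2 size factors within edgeR, library size alone, no low-count filter, an adjusted p under 0.01, only the groups compared in the fit, the replicate number as a block, leaving out each library in turn, fry in place of camera, and leaving out the mitochondrial chromosome. Removing from each library its trend on GC content, genomic span and exonic length, with and without the block, was added after the data were examined; it covered 11598 genes above a mean log2 CPM of 2 with a GC value. List results were recomputed where the list was called, and those of the ATF4 targets in every comparison. Overlaps between comparisons with the same control libraries were set beside 20 simulations of unchanged groups; controls of 3 libraries cannot be split into parts with at least 2 each.

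The tests were tested on simulated data drawn from the real genes' means and spread, with 200 changed genes among 21086. For day 9 against doxycycline, 54% of genes changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 3-fold or 4-fold were called, with 15 of 20850 unchanged genes. For the difference between lines at day 9, the shares were 34%, 80%, 94% and 100%, with 8 unchanged genes called. In the same simulation at day 9, camera called the list shifted 1.3-fold and 1 of the other lists, and 1 unshifted list in the parental comparison. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for loading and plots.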

Results

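Gene expression was measured in 18 libraries of HAP1 cells in 6 groups of 3. The series compares cells that express SARS2, the seryl-transfer RNA synthetase of mitochondria, which charges mitochondrial serine transfer RNAs for protein synthesis inside the organelle, with cells labelled as 3, 6 or 9 days without its expression. The parental line was measured with and without 15 ng/mL doxycycline. The line with SARS2 deleted and a tagged SARS2 transgene (the deleted line below) was measured with doxycycline and in groups labelled 3, 6 and 9 days after its removal. Libraries held 66850705 to 111123481 counts.

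Counts assigned to SARS2 (chromosome 19, 38915266 to 38930763, minus strand, GRCh38) were on average not lower in any deleted-line group labelled as lacking doxycycline than in the deleted line with it. SARS2 stood at 24.2 ± 0.923 CPM (SD, n = 3) in the deleted line with doxycycline, 31.6 ± 0.986 at day 3, 24.7 ± 1.3 at day 6 and 41.8 ± 7.16 at day 9. In the parental line it stood at 44.3 ± 1.67 with doxycycline and 39.9 ± 3.03 without. Against doxycycline in the deleted line, SARS2 rose at day 9 (log2 fold change 0.79 ± 0.10 SE, adjusted p = 2.7e-06) and at day 3 (0.38 ± 0.10, adjusted p = 0.014). Day 6 gave 0.03 ± 0.10 (adjusted p = 0.86). The day 3 call was lost without day 3 replicate 2 (0.38), day 3 replicate 3 (0.37) or deleted-line doxycycline replicate 1 (0.36). With doxycycline, SARS2 was lower in the deleted than in the parental line (−0.87 ± 0.10, adjusted p = 3.5e-06), and the parental line without against with doxycycline gave −0.15 ± 0.10 (adjusted p = 0.22). Because a fall was not seen where the labels state loss of expression, groups are given here as the libraries labelled with each day, and directions over days rest on those labels. Transgene reads and reads of the deleted locus cannot be separated in these counts.

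**Figure D1:**
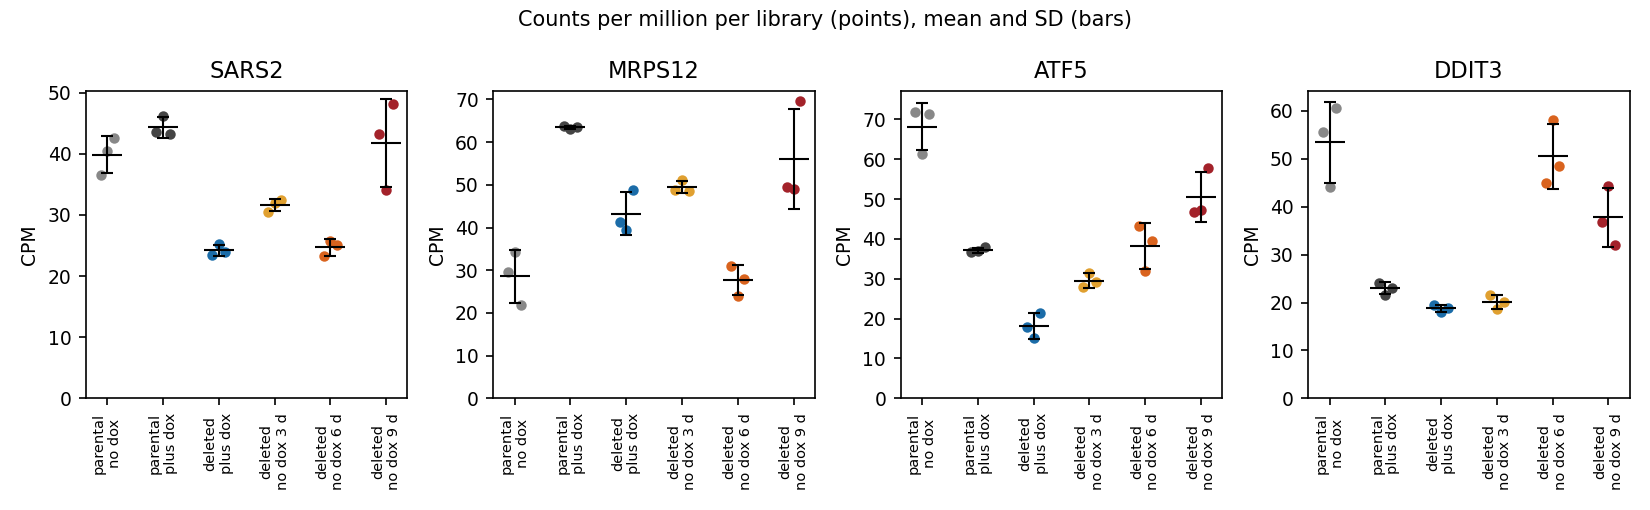
CPM (y axis) of SARS2, its neighbour MRPS12, and the stress transcription factors ATF5 and DDIT3 in each library (points), with mean and SD (bars, n = 3) for the 6 groups. SARS2 means run from 24.2 CPM in the deleted line with doxycycline to 44.3 CPM in the parental line with doxycycline.

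Neighbours of SARS2 moved by group as well. MRPS12 (38930944 to 38933168, plus strand), a mitochondrial ribosomal protein gene starting next to SARS2 on the opposite strand, was at 43.3 ± 5.02 CPM in the deleted line with doxycycline and 27.7 ± 3.50 in libraries labelled day 6 (−0.64 ± 0.14, adjusted p = 0.0025). In the parental line MRPS12 was at 63.5 ± 0.369 with and 28.6 ± 6.26 CPM without doxycycline (−1.15 ± 0.14, adjusted p = 7.6e-06). Its day 9 rise of 0.37 (adjusted p = 0.038) was lost without day 9 replicate 3 (0.19) or deleted-line doxycycline replicate 1 (0.34) or 2 (0.31), and was 0.16 with the GC and length trend removed. NFKBIB (38899666 to 38908889), an inhibitor of NF-kB, rose at day 9 (0.52, adjusted p = 0.0036), a call lost with that trend removed (0.29), and fell in the parental line without doxycycline (−1.08, adjusted p = 8e-06). SIRT2 (38878555 to 38899618), a deacetylase, was lower in the deleted line (−0.36, adjusted p = 0.0013). CCER2 (38908980 to 38912186) rose in the parental line without doxycycline (1.16, adjusted p = 0.0021), and FBXO17 (38941401 to 38975742) was at or below 0.247 CPM on average in every group.

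The 6 groups separated on the first 2 principal components of log2 CPM. The libraries labelled day 6 and day 9 lay at opposite ends of the deleted line, with those labelled day 3 between doxycycline and day 9. Fold changes also followed the genomic span of genes, from the start to the end of the gene with introns. Across 11598 genes, which are not independent replicates, Spearman's rho with span was 0.36 at day 6, −0.36 at day 9, −0.06 at day 3 and 0.30 in the parental line without doxycycline. NEAT1, a long RNA retained in the nucleus, moved with these groups and was chosen after its values were seen. It went from 6.86 ± 0.313 CPM with doxycycline to 16.3 ± 2.84 at day 6 (1.25 ± 0.18, adjusted p = 6.6e-05) and 2.90 ± 1.01 at day 9 (−1.24 ± 0.19, adjusted p = 2.6e-05). In the parental line NEAT1 went from 3.94 ± 0.30 with to 14.6 ± 1.83 CPM without doxycycline (1.89 ± 0.19, adjusted p = 6.5e-07). MALAT1, another nuclear RNA, gave 0.12 at day 6 (adjusted p = 0.53), −0.08 at day 9 (adjusted p = 0.65; −0.33 and passing without day 9 replicate 1) and 0.60 in the parental line (adjusted p = 0.0015).

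**Figure D2:**
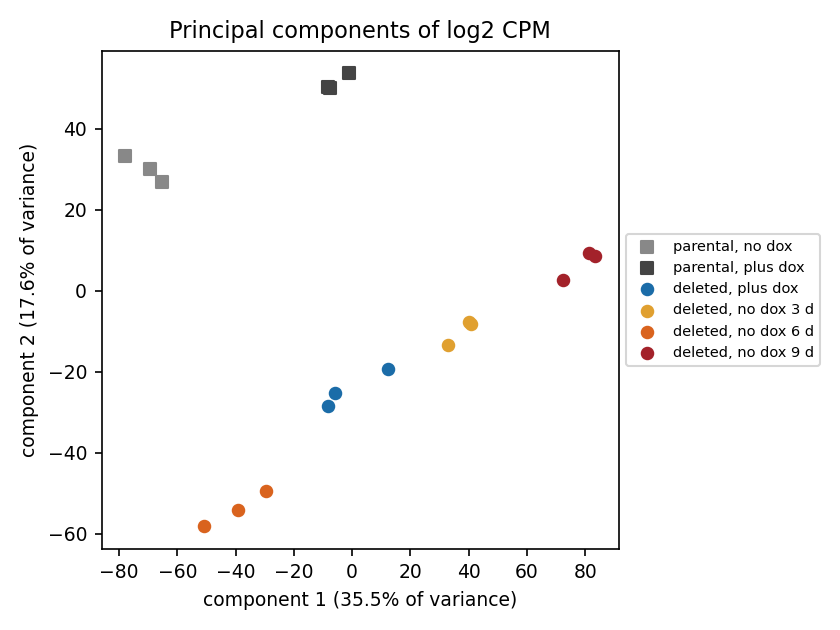
Principal component 1 (x axis, 35.5% of variance) against component 2 (y axis, 17.6%) of log2 CPM for the 18 libraries, coloured by group, squares for the parental line and circles for the deleted line. Parental libraries lie above those of the deleted line on component 2, and within the deleted line component 1 runs from day 6 through doxycycline and day 3 to day 9.

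The comparison of day 3 with doxycycline asks what differed in the deleted line at that label. In the libraries labelled day 3, 18 of 37 targets of ATF4, which drives amino acid transport and synthesis genes in the integrated stress response, rose. So did 11 of 33 genes for building ribosomes, and 33 of 78 genes for proteins of the cytosolic ribosome fell. With an estimated correlation between genes none of these lists was called (adjusted p = 0.06, adjusted p = 0.68 and adjusted p = 0.68). Of the ATF4 targets, 1 fell and 18 did not pass (19 higher and 1 lower adjusted over the list alone). ATF4 targets had a median of 0.28 (camera adjusted p = 1e-07). They included the amino acid transporters SLC7A5 (0.52, adjusted p = 0.00011; 245 to 351 CPM), SLC6A9 (0.74, adjusted p = 0.00016) and SLC38A2 (0.36, adjusted p = 0.00087), and the stress sensor SESN2 (0.42, adjusted p = 0.0012). ATF5, a transcription factor of the mitochondrial stress response (chromosome 19, 49928906 to 49933935), rose by 0.70 ± 0.12 (adjusted p = 0.0013). ATF4 itself (chromosome 22, 39520559 to 39522686) rose by 0.25 ± 0.06 (adjusted p = 0.0091), and DDIT3, the stress factor CHOP (chromosome 12, 57516588 to 57521698), gave 0.09 (adjusted p = 0.67). The member that fell, KLHL24, an adaptor of a ubiquitin ligase (−0.63, adjusted p = 0.031), lost its call without any 1 of the day 3 replicates (−0.59 to −0.68) or without deleted-line doxycycline replicate 1 (−0.52) or 2 (−0.60).

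Of 78 cytosolic ribosome genes, 33 fell, 1 rose and 44 did not pass at day 3 (59 lower and 2 higher adjusted over the list alone). Cytosolic ribosome genes had a median of −0.22 (camera adjusted p = 1.9e-15). Among them were RPL13A (−0.36, adjusted p = 0.0015; 2570 to 2000 CPM), RPS3A (−0.39), RPS18 (−0.33) and RPS15A (−0.37). RPS10, which rose (0.45, adjusted p = 0.036), lost its call without any 1 of the day 3 replicates (0.35 to 0.52) or deleted-line doxycycline replicate 1 (0.33) or 2 (0.43). Of 33 ribosome biogenesis genes, 11 rose and 22 did not pass (19 higher and 1 lower adjusted over the list alone). Ribosome biogenesis genes had a median of 0.28 (camera adjusted p = 1.4e-06, and not called by fry with an adjusted p of 0.065). Among them were CAD, which starts pyrimidine synthesis (0.46, adjusted p = 0.00056), the ribosomal RNA methyltransferase NOP2 (0.54, adjusted p = 0.0024), the RNA polymerase I subunit POLR1A (0.48) and RRP12 (0.58).

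Among single genes at day 3, the largest rises were in DOK3, an adaptor of immune receptor signalling (1.66 ± 0.20, adjusted p = 0.00011; 2.26 to 7.13 CPM), LGSN (1.43), IGSF10 (1.21), the oxytocin receptor gene OXTR (1.17; 2.49 to 5.59 CPM) and FBXL19-AS1 (1.15). The largest falls were in MVP, the major vault protein (−2.06 ± 0.27, adjusted p = 0.00022; 5.44 to 1.3 CPM), the kinase gene PNCK (−1.58), TXNIP (−1.50), the synaptic vesicle gene SYT1 (−1.46) and LGALS1, galectin-1 (−1.34). TXNIP, a glucose-responsive inhibitor of thioredoxin and glucose uptake, went from 25.2 ± 6.36 to 8.94 ± 0.298 CPM (± 0.16 SE of the fold change, adjusted p = 5.4e-05). In all, 2889 genes of 21615 passed, 1405 higher and 1484 lower, 200 and 207 of them at least 2-fold. Of these, 48.6% were higher, against 52.2% with library size alone. The share was 60.2% with the GC and length trend removed, in a fit of 11598 genes only. The count fell to 1088 without day 3 replicate 3, 1328 without day 3 replicate 2, 1125 without deleted-line doxycycline replicate 1 and 1426 without replicate 2.

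In the libraries labelled day 6, 34 of 37 ATF4 targets rose, while 61 of 80 genes for mitochondrial ribosomes, 32 of 41 for respiratory complexes II to V, 25 of 37 for complex I, 72 of 78 for cytosolic ribosomes and 17 of 23 for cholesterol synthesis fell. With an estimated correlation the ATF4 list held (adjusted p = 0.00041) and the others did not (adjusted p = 0.16 for each). Of the 37 ATF4 targets, 34 rose and 3 did not pass (35 higher and 1 lower adjusted over the list alone). ATF4 targets had a median of 0.69 (camera adjusted p = 5.7e-24). Among them STC2, a secreted glycoprotein, doubled (1.09 ± 0.06, adjusted p = 2.9e-09; 93.4 to 199 CPM), and the pseudokinase TRIB3 (1.22, adjusted p = 6.5e-08), the hormone gene ADM2 (1.45, adjusted p = 1.5e-07) and SESN2 (0.87) rose. ATF5 rose by 1.07 (adjusted p = 7.2e-06) and DDIT3 by 1.43 ± 0.12 (adjusted p = 4.6e-07; 18.8 ± 0.742 to 50.5 ± 6.75 CPM). ATF4 rose by 0.20 (adjusted p = 0.018), a call lost without day 6 replicate 2 (0.16) or deleted-line doxycycline replicate 3 (0.20).

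Of 80 mitochondrial ribosome genes, 61 fell and 19 did not pass (64 lower adjusted over the list alone). Mitochondrial ribosome genes had a median of −0.34 (camera adjusted p = 3.5e-19). Among them were MRPS15 (−0.66, adjusted p = 2.2e-06), MRPL27 (−0.75, adjusted p = 6.6e-06; 31.6 to 18.8 CPM), MRPL53 (−0.67) and MRPS21 (−0.57). Of 41 nuclear genes of respiratory complexes II to V, 32 fell (35 adjusted over the list alone). Genes of complexes II to V had a median of −0.42 (camera adjusted p = 8.1e-16). Among them were the ATP synthase subunits ATP5MC3 (−0.60), ATP5MC1 (−0.66), ATP5MG (−0.63) and ATP5PB (−0.52). Of 37 complex I genes, 25 fell (28 adjusted over the list alone). Complex I genes had a median of −0.33 (camera adjusted p = 3e-12). Of 78 cytosolic ribosome genes, 72 fell (75 adjusted over the list alone). Cytosolic ribosome genes had a median of −0.36 (camera adjusted p = 2.7e-24). Among them were RPL17 (−0.79), RPL27 (−0.55, adjusted p = 4.2e-05), RPSA (−0.47) and RPL35 (−0.52). With the GC and length trend removed, these medians were −0.15 for the mitochondrial ribosome, −0.13 for complexes II to V, −0.11 for complex I and −0.11 for the cytosolic ribosome, and RPSA (−0.10) and RPL35 (−0.22) lost their calls. The named members that kept a call were then at −0.30 (MRPS15), −0.32 (MRPL27), −0.30 (MRPL53), −0.31 (MRPS21), −0.25 (ATP5MC1), −0.25 (ATP5MG), −0.34 (ATP5PB), −0.41 (RPL17) and −0.19 (RPL27).

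Cholesterol synthesis genes fell at day 6 in 17 of 23 cases, with 6 not passing (19 lower adjusted over the list alone). Cholesterol synthesis genes had a median of −0.56 (camera adjusted p = 2.4e-11). Among them were FDPS, which makes farnesyl diphosphate (−0.76, adjusted p = 5.4e-07; 315 to 186 CPM), LSS, which closes the sterol rings (−0.71), and NSDHL (−0.73). Fatty acid synthesis genes fell in 10 of 13 cases (11 adjusted over the list alone). Fatty acid synthesis genes had a median of −0.42 (camera adjusted p = 3.8e-07, adjusted p = 0.16 with an estimated correlation). The largest rises of single genes were in GDF15, a stress-induced cytokine (chromosome 19, 18386158 to 18389176; 3.88 ± 0.34, adjusted p = 4.5e-07; 0.669 to 9.97 ± 0.474 CPM), the chloride channel gene BEST1 (3.55, adjusted p = 2.9e-09; 2.78 to 32.4 CPM) and DMGDH, a mitochondrial dimethylglycine dehydrogenase (3.21, adjusted p = 6.3e-09; 1.99 to 18.4 CPM). They were followed by INHBE, an inhibin subunit (3.11; 1.60 to 13.8 CPM), and DEPP1 (2.86). ANXA1, annexin A1, fell from 65.1 ± 11.1 to 25.1 ± 4.44 CPM (−1.37 ± 0.13, adjusted p = 8.9e-07), and SNORA50C (−1.3) and TLCD1 (−1.22) fell. RMRP, the RNA of a ribonuclease complex (−1.56, adjusted p = 0.034), lost its call without day 6 replicate 2 (−1.34) or 3 (−1.29) or any deleted-line doxycycline replicate (−1.50 to −1.60) and was at −2.27 without day 6 replicate 1. The pseudogene RPL41P5 (−1.34, adjusted p = 0.03) lost its call without day 6 replicate 1 (−1.25) or 3 (−0.95) or deleted-line doxycycline replicate 2 (−1.26) or 3 (−1.27), was at −2.03 without day 6 replicate 2, and lost it with the GC and length trend removed (−0.98).

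At day 6, 6070 genes passed, 3034 higher and 3036 lower, with 640 and 228 of them at least 2-fold. With libraries scaled by size alone, the share of higher genes was 64.3% against 50%. The nuclear RNA NEAT1 was raised here as well (1.25). Without deleted-line doxycycline replicate 3 the count was 3834. Among markers of other cell types, 4 of 10 epithelial genes rose (median 0.87, camera adjusted p = 0.0025, adjusted p = 0.16 with an estimated correlation). Of 16 mesenchymal genes, 7 rose and 2 fell (median 0.41, and 0.17 with the trend removed, camera adjusted p = 0.016, adjusted p = 0.16 with an estimated correlation).

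In the libraries labelled day 9, 30 of 37 ATF4 targets, 29 of 34 genes of DNA replication, 26 of 33 of ribosome biogenesis, 5 of 5 metallothioneins and 12 of 20 genes of the unfolded protein response rose, and 16 of 23 cholesterol synthesis genes fell. With an estimated correlation the ATF4 list held (adjusted p = 0.01) and the others did not (in this order, adjusted p = 0.17, 0.63, 0.32, 0.61 and 0.63). Of the ATF4 targets, 2 fell and 5 did not pass (30 higher and 2 lower adjusted over the list alone). ATF4 targets had a median of 0.75 (camera adjusted p = 8.2e-12). They included SESN2 (1.28, adjusted p = 6.1e-10; 29.4 to 71.2 CPM), SLC6A9 (1.57, adjusted p = 9.7e-10), SLC7A5 (1.04, adjusted p = 1.1e-09) and CHAC1, which breaks down glutathione (2.10 ± 0.13, adjusted p = 1.7e-09; 11.4 to 49 ± 10.8 CPM). ATF5 rose by 1.48 (adjusted p = 3.3e-08; 18.2 ± 3.17 to 50.6 ± 6.30 CPM) and DDIT3 by 1.01 (adjusted p = 2.5e-06). KLHL24 fell by 1.57 (adjusted p = 2.1e-06). The amino acid transporter SLC43A1 (−0.23, adjusted p = 0.032) lost its call without day 9 replicate 2 (−0.22) or 3 (−0.17) or deleted-line doxycycline replicate 1 (−0.23) or 2 (−0.18), and was at −0.35 with the GC and length trend removed. The ATF4 gene was at 0.17 (adjusted p = 0.029), lost without day 9 replicate 3 (0.12) or any deleted-line doxycycline replicate (0.16 to 0.17), was at 0.10 and not passing with library size alone, and turned to −0.03 with the GC and length trend removed.

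Of 34 DNA replication genes, 29 rose, 1 fell and 4 did not pass at day 9 (29 and 1 adjusted over the list alone). DNA replication genes had a median of 0.33 (camera adjusted p = 2.7e-09). At day 6, 16 had fallen and 1 risen (19 and 1 adjusted over the list alone; median −0.16, camera adjusted p = 5.9e-05, adjusted p = 0.16 with an estimated correlation). Those that rose at day 9 included thymidine kinase TK1 (0.95, adjusted p = 6.5e-08), the ribonucleotide reductase subunit RRM2 (0.66), FEN1 (0.62) and CDC6 (0.58). The helicase subunit MCM6 fell by 0.19 (adjusted p = 0.041), a call lost without day 9 replicate 1 (−0.21) or 2 (−0.09) or any deleted-line doxycycline replicate (−0.16 to −0.20), and with no low-count filter (−0.18). Of 33 ribosome biogenesis genes, 26 rose, 1 fell and 6 did not pass (27 and 1 adjusted over the list alone). Ribosome biogenesis genes had a median of 0.46 (camera adjusted p = 4.7e-07). Among them were CAD (0.79, adjusted p = 7.2e-08), PPAN (1.61, adjusted p = 1.1e-07), NOP2 (1.01) and RRP12 (1.25). MYC, the transcription factor the list is named for, fell from 1130 ± 115 to 717 ± 66 CPM (−0.65 ± 0.11, adjusted p = 5.8e-05). Mitochondrial ribosome genes, lower at day 6, rose at day 9 in 30 of 80 cases and fell in 4 (28 and 2 adjusted over the list alone). Mitochondrial ribosome genes had a median of 0.17 (camera adjusted p = 0.00063, adjusted p = 0.65 with an estimated correlation). That list call was lost with the GC and length trend removed (median 0.12).

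Of 23 cholesterol synthesis genes, 16 fell, 1 rose and 6 did not pass at day 9 (16 and 1 adjusted over the list alone). Cholesterol synthesis genes had a median of −0.67 (camera adjusted p = 0.00016). INSIG1, the sterol-regulated brake on this pathway, fell from 116 to 27.8 CPM (−2.06 ± 0.21, adjusted p = 3.2e-07), and squalene synthase FDFT1 (−1.06), its regulator SREBF2 (−0.81) and MSMO1 (−1.60) fell. TM7SF2 (0.39, adjusted p = 0.043) lost its call without day 9 replicate 1 (0.34) or 2 (0.20), or deleted-line doxycycline replicate 1 (0.33) or 2 (0.36), was at 0.59 without day 9 replicate 3, and lost it also with the trend removed (0.19). All 5 tested metallothioneins, metal-binding proteins, rose (5 adjusted over the list alone). Metallothioneins had a median of 1.06 (camera adjusted p = 0.00044). At day 6, 4 of 5 had fallen (5 adjusted over the list alone; median −0.91, and −0.55 with the trend removed; camera adjusted p = 0.00011, adjusted p = 0.16 with an estimated correlation). At day 9 MT1E was at 110 CPM, against 45.9 with doxycycline (1.27, adjusted p = 4e-07), with MT2A at 0.89, MT1X at 1.06 and MT1F at 1.25. Of 20 genes of the unfolded protein response, 12 rose, 1 fell and 7 did not pass (12 and 1 adjusted over the list alone). Genes of the unfolded protein response had a median of 0.32 (camera adjusted p = 0.00054). Among them were SYVN1, a ubiquitin ligase of the endoplasmic reticulum (0.75, adjusted p = 3.3e-07), the chaperones HYOU1 (0.68) and CALR (0.61; 708 to 1080 CPM), and HERPUD1 (0.74). EDEM1 (−0.18, adjusted p = 0.042) lost its call without day 9 replicate 2 (−0.11) or deleted-line doxycycline replicate 1 (−0.17) or 2 (−0.14).

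The largest rises of single genes at day 9 included DOK3 (chromosome 5, 177501904 to 177511100; 3.53 ± 0.21, adjusted p = 9.1e-10; 2.26 to 26.1 ± 3.15 CPM), INHBE (3.67, adjusted p = 2.2e-08; 1.60 to 20.4 ± 11 CPM) and DUSP6, a phosphatase of the kinase ERK (3.56, adjusted p = 1.7e-07; 0.687 to 8.09 ± 4.03 CPM). ETV5, a transcription factor induced by ERK signalling, rose as well (2.65, adjusted p = 4.7e-07; 0.929 to 5.81 CPM). So did PRKXP1 (2.97), PRR22 (2.90), MIR22HG (2.55), NHSL1-AS1 (2.43) and AMH, anti-Müllerian hormone (2.37; 2.43 to 12.6 CPM). SMIM11 rose by 4.21 ± 0.79 (adjusted p = 0.00024), but stood at 1.66, 40.4 and 22.8 CPM in the day 9 replicates and gave 3.39 without replicate 2. The largest falls were in the immunoglobulin kappa locus IGK (−3.49, adjusted p = 1.7e-09; 6.94 to 0.621 CPM), MVP (−2.76), SYT1 (−2.75 ± 0.15, adjusted p = 4e-10; 13.4 to 2 CPM, and −2.09 with the GC and length trend removed) and the noncoding RNA OLMALINC (−2.54; 63.6 to 10.9 CPM). Next came PNCK (−2.52), the tight junction gene TJP3 (−2.50, and −3.27 without day 9 replicate 2), CELF5 (−2.45), FER1L4 (−2.31), SRSF11P1 (−2.29) and ZC3H6 (−2.29 ± 0.14, adjusted p = 1.1e-09; 55.2 to 11.3 CPM). In all, 10027 genes passed, 4877 higher and 5150 lower, 1069 and 1613 of them at least 2-fold. The share of higher genes was 48.6%, 41.5% with library size alone and 53.5% with the GC and length trend removed, and the nuclear RNA NEAT1 was lowered (−1.24).

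**Figure D3:**
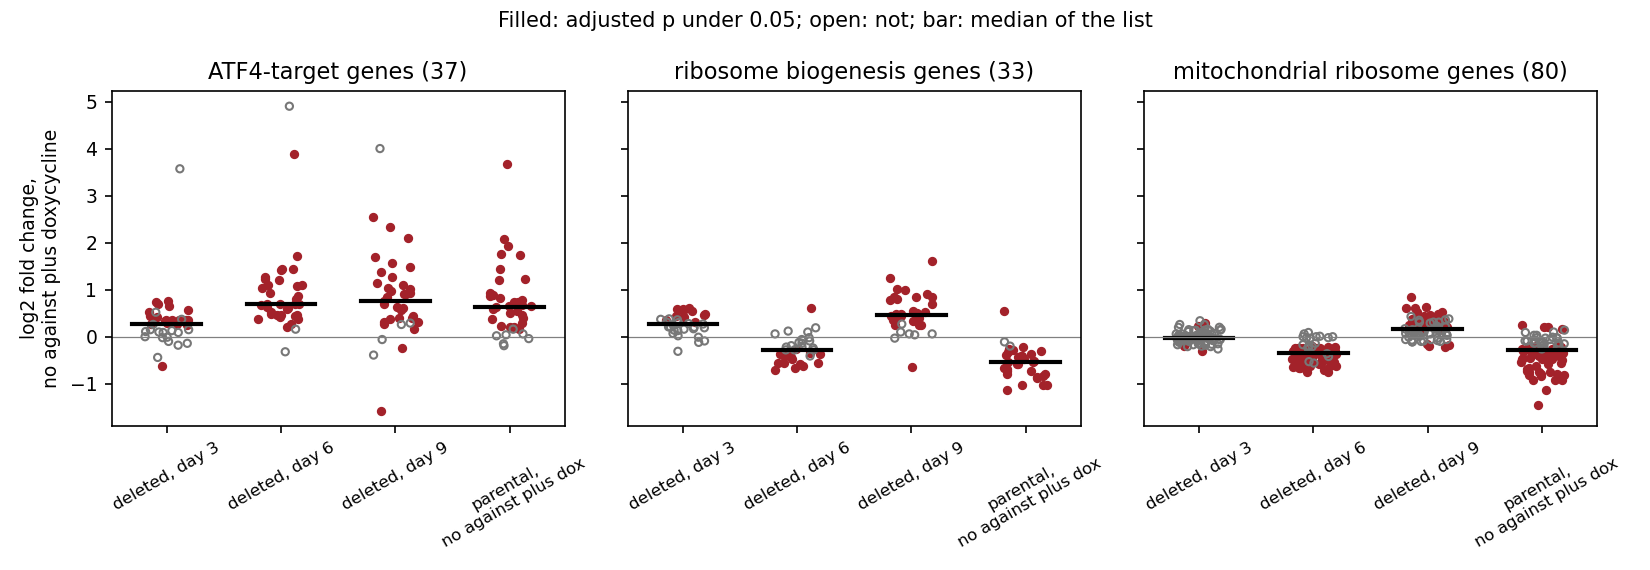
Log2 fold change (y axis) of each member of 3 gene lists, ATF4 targets (37), ribosome biogenesis (33) and mitochondrial ribosome (80), for days 3, 6 and 9 in the deleted line and for the parental line, each without against with doxycycline; filled points passed the test, open points did not, and bars are medians. ATF4 targets have medians of 0.28, 0.69, 0.75 and 0.64, while those of ribosome biogenesis are 0.28, −0.28, 0.46 and −0.53, with members on both sides of 0 (15 of 33 lower and 2 higher at day 6, where the list was not called with an estimated correlation, adjusted p = 0.38).

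Between successive days, 28 of 37 ATF4 targets were higher in the libraries labelled day 6 than in those labelled day 3, and 29 of 33 ribosome biogenesis and 11 of 12 heat shock genes were lower. With an estimated correlation the ATF4 list held (adjusted p = 0.037) and the others did not (adjusted p = 0.33 and adjusted p = 0.32). ATF4 targets rose in 28 of 37 cases, fell in 1 and did not pass in 8 (28 and 1 adjusted over the list alone). ATF4 targets had a median of 0.45 (camera adjusted p = 5.9e-09). ADM2 rose by 1.46, STC2 by 0.74 and DDIT3 by 1.33 (adjusted p = 2.2e-07). CBS, which starts the conversion of homocysteine to cysteine, fell by 0.41 (adjusted p = 0.017), a call lost without day 6 replicate 2 (−0.30). Of 33 ribosome biogenesis genes, 29 fell and 1 rose (31 and 1 adjusted over the list alone). Ribosome biogenesis genes had a median of −0.58 (camera adjusted p = 7.7e-10). Among them were nucleolin NCL (−0.82), NOP16 (−0.95) and UTP4 (−0.74), while MYC rose from 910 to 1720 CPM (0.92, adjusted p = 2.4e-06). Of 12 heat shock genes, 11 fell (11 adjusted over the list alone). Heat shock genes had a median of −0.58 (camera adjusted p = 3.5e-05). Among them were the chaperone HSP90AA1 (−0.96, adjusted p = 2.4e-07; 3780 to 1940 CPM), DNAJB1 (−0.95), DNAJA1 (−0.98) and HSPH1 (−0.92). DEPP1 (4.64), GDF15 (4.32), DMGDH (3.91), BEST1 (3.47) and DLK1 (3.31, adjusted p = 1e-08) rose most, and LGSN (−3.18), IGSF10 (−3.08), DOK3 (−2.41), LRRN3 (−2.31) and LINC01963 (−2.07) fell most. In all, 9234 genes passed, 4734 higher and 4500 lower. Higher ones made up 51.3%, 59.7% with library size alone and 47.5% with the trend removed.

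From day 6 to day 9, 72 of 80 mitochondrial ribosome and 32 of 33 ribosome biogenesis genes were higher at the later label, but neither list was called with an estimated correlation (adjusted p = 0.41 and adjusted p = 0.43). Of 80 mitochondrial ribosome genes, 72 rose, 2 fell and 6 did not pass (75 and 2 adjusted over the list alone). Mitochondrial ribosome genes had a median of 0.56 (camera adjusted p = 1.4e-13). Among them were MRPL27 (1.24, adjusted p = 8.8e-10), MRPS11 (0.94), MRPS15 (0.87) and MRPL49 (0.79). With the GC and length trend removed the median was 0.27, MRPL27 was at 0.77, MRPS15 at 0.43 and MRPL49 at 0.39. The members that fell were PTCD3, a pentatricopeptide protein of the small subunit (−0.24, adjusted p = 0.0021, and −0.37 with library size alone), and MRPS5 (−0.20, adjusted p = 0.0065), whose call was lost without day 6 replicate 2 (−0.16). Of 33 ribosome biogenesis genes, 32 rose and MYC fell (32 and 1 adjusted over the list alone). Ribosome biogenesis genes had a median of 0.71 (camera adjusted p = 1e-09). ODC1, which starts polyamine synthesis, was at 1.27, NOP2 at 1.19, NHP2 at 0.67 (0.20 with the trend removed) and MYC at −1.26 (adjusted p = 1.2e-08). ATF4 targets went both ways, 13 higher and 11 lower (median 0.01, camera adjusted p = 0.95).

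Of 10 epithelial markers, 7 fell and 1 rose from day 6 to day 9 (7 and 1 adjusted over the list alone). Epithelial markers had a median of −1.14 (camera adjusted p = 0.045, adjusted p = 0.43 with an estimated correlation; the list call was lost without day 6 replicate 1, at −1.11, or day 9 replicate 3, at −1.10). The splicing regulator ESRP1 went from 11.6 to 5.26 CPM (−1.14, adjusted p = 1e-07), CDH3 from 1.03 to 0.11 CPM and CLDN4 from 0.412 to 0.0456 CPM. The keratin KRT18 rose from 36.5 to 56.2 CPM (0.62, adjusted p = 3.2e-05; 0.19 with the GC and length trend removed). DOK3 rose most steeply (4.28 ± 0.22, adjusted p = 2.9e-11; 1.34 to 26.1 CPM), with PRR22 (4.04), DUSP6 (3.10), AMH (3.08) and PRKXP1 (3.03). DMGDH (−4.69, adjusted p = 1.9e-11; 18.4 to 0.71 CPM), PNCK (−3.99), LINC00663 (−3.95) and LGI4 (−3.76) were among the genes that fell most. In all, 12709 genes passed, 6183 higher and 6526 lower. With libraries scaled by size alone, which shifts the median of all genes by −0.127, the share of higher genes was 38.6% against 48.7%. It was 51.5% with the trend removed.

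The parental line without against with doxycycline measures what the drug's removal went with where no transgene is present. How long those cells had been without doxycycline is not given in the sources used here. In the libraries labelled as lacking doxycycline, 30 of 37 ATF4 targets and 12 of 18 hypoxia genes were higher, and 30 of 33 ribosome biogenesis, 12 of 12 heat shock and 50 of 80 mitochondrial ribosome genes were lower. With an estimated correlation the ATF4 list held (adjusted p = 0.012) and the others did not (adjusted p = 0.11 for hypoxia and adjusted p = 0.38 for each of the rest). Of 37 ATF4 targets, 30 rose and 7 did not pass (30 adjusted over the list alone). ATF4 targets had a median of 0.64 (camera adjusted p = 1e-11). Among them were CHAC1 (1.92 ± 0.13, adjusted p = 2.5e-08; 20.4 to 77.1 CPM), DDIT4, an inhibitor of the growth kinase mTORC1 (1.73, adjusted p = 2.2e-07; 46.1 to 153 CPM), VLDLR (0.83) and CTH (0.74). ATF5 rose by 0.88 (adjusted p = 1.7e-05; 37.2 ± 0.653 to 68.2 ± 5.97 CPM) and DDIT3 by 1.22 (adjusted p = 8.2e-07; 23.0 ± 1.25 to 53.5 ± 8.50 CPM). ATF4 was at 0.17 (adjusted p = 0.029), lost without replicate 3 lacking doxycycline (0.11) or doxycycline replicate 2 (0.14) or 3 (0.17). Of 18 hypoxia genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone). Hypoxia genes had a median of 0.55 (camera adjusted p = 1.5e-05). Among them were the collagen prolyl hydroxylases P4HA2 (0.82) and P4HA1 (0.96), PDK1, which restrains pyruvate entry into mitochondria (0.68), and BNIP3 (0.54). EGLN3, an oxygen sensor, fell by 0.40 (adjusted p = 0.025), a call lost without replicate 1 (−0.41) or 3 (−0.28) lacking doxycycline or doxycycline replicate 1 (−0.38) or 2 (−0.40), and with library size alone (−0.35).

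Of 33 ribosome biogenesis genes in the parental line, 30 fell and MYC rose (31 and 1 adjusted over the list alone). Ribosome biogenesis genes had a median of −0.53 (camera adjusted p = 1e-11). Among them were ODC1 (−1.13, adjusted p = 5.4e-07), UTP4 (−0.73), POLR1A (−0.85) and PES1 (−1.02), with MYC at 0.54 (adjusted p = 0.00056). All 12 heat shock genes fell (12 adjusted over the list alone). Heat shock genes had a median of −0.51 (camera adjusted p = 1.5e-05). Among them were HSP90AA1 (−0.79, adjusted p = 3.3e-06), HSPH1 (−1.13), DNAJB1 (−0.79) and HSPA8 (−1.07). Of 80 mitochondrial ribosome genes, 50 fell, 4 rose and 26 did not pass (55 and 4 adjusted over the list alone). Mitochondrial ribosome genes had a median of −0.28, and −0.17 with the GC and length trend removed (camera adjusted p = 4.7e-11). Among them were MRPL1 (−1.45, adjusted p = 1.2e-06; 45.7 to 16.7 CPM), MRPS16 (−0.48), MRPL12 (−1.13) and MRPL57 (−0.81). The 4 that rose lost their calls when libraries were left out. MRPL10 (0.20) lost it without replicate 2 (0.16) or 3 (0.17) lacking doxycycline or doxycycline replicate 2 (0.18) or 3 (0.18), and MRPL42 (0.21) without replicate 1 lacking it (0.16) and with the GC and length trend removed (0.01). MRPL48 (0.25) lost it without replicate 3 lacking doxycycline (0.19) or doxycycline replicate 2 (0.22), and MRPS14 (0.17) without replicate 1 (0.13) or 3 (0.16) lacking it or any doxycycline replicate (0.15 to 0.18).

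TXNIP (chromosome 1, 145992435 to 145996579), which fell at day 3 in the deleted line, rose most in the parental line without doxycycline, from 18.4 ± 1.22 to 171 ± 20.1 CPM (3.22 ± 0.17, adjusted p = 7.6e-10). It was followed by DEPP1 (2.87), the interferon-induced IFITM1 (2.55; 1.51 to 8.87 CPM), KANK4 (2.41) and MVP (2.38). The p53-induced gene TP53I3 fell from 10.7 to 2.84 CPM (−1.91 ± 0.17, adjusted p = 2.4e-07), and RPS10 (−1.85) and SNORA50C (−1.85, and −1.20 with the GC and length trend removed) fell. RPPH1, the RNA of ribonuclease P, fell by 2.38 (adjusted p = 0.0015), and by 1.39 without doxycycline replicate 3. The ribosomal RNA gene RNA45SN2 (−1.94, adjusted p = 0.041) lost its call without replicate 1 (−2.04) or 3 (−1.39) lacking doxycycline or doxycycline replicate 3 (−1.23), and was at −2.66 without replicate 2 lacking it. It also lost it with the DESeq2 test (−1.95) and with only both groups in the fit (−1.96). In all, 8519 genes passed, 4540 higher and 3979 lower, 1123 and 601 of them at least 2-fold. Higher ones made up 53.3%, 60.2% with library size alone and 46.6% with the GC and length trend removed, and the nuclear RNA NEAT1 was raised (1.89).

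With doxycycline in both, the deleted line with its transgene is compared with the parental line before any removal. Of their genes, 23 of 37 ATF4 targets and 15 of 22 glycolysis genes were lower in the deleted line, and 8 of 16 markers of mesenchymal cells were higher. With an estimated correlation the ATF4 list held (adjusted p = 0.0066) and the others did not (adjusted p = 0.2 and adjusted p = 0.072). Of 37 ATF4 targets, 23 were lower, 2 higher and 12 did not pass (28 and 2 adjusted over the list alone). ATF4 targets had a median of −0.41 (camera adjusted p = 5e-13). Among them were SLC7A5 (−0.75, adjusted p = 8e-08), DDIT4 (−1.36, adjusted p = 3.3e-06), GPT2, an alanine aminotransferase (−0.55), and ATF5 (−1.03, adjusted p = 7.4e-06). ATF4 was lower as well (−0.49, adjusted p = 1e-05; 563 ± 23.1 against 400 ± 0.651 CPM), and DDIT3 gave −0.29 (adjusted p = 0.11). The members that were higher were KLHL24 (0.96, adjusted p = 0.0012) and GDF15 (1.59, adjusted p = 0.0076), whose call was lost with limma-voom (1.60). Of 22 glycolysis genes, 15 were lower and 7 did not pass (17 adjusted over the list alone). Glycolysis genes had a median of −0.28 (camera adjusted p = 9.1e-07). Among them were the glucose transporters SLC2A3 (−1.11; 13.3 against 6.18 CPM) and SLC2A1 (−0.59), hexokinase HK2 (−0.50) and enolase ENO1 (−0.32). Of 16 mesenchymal markers, 8 were higher and 8 did not pass (9 adjusted over the list alone). Mesenchymal markers had a median of 0.37 (and 0.23 without deleted-line replicate 1; camera adjusted p = 0.00015, adjusted p = 0.072 with an estimated correlation). Among them were the receptor PDGFRA (1.80 ± 0.08, adjusted p = 7.6e-12; 11.1 against 38.8 CPM), LOXL2 (0.79), vimentin VIM (0.43) and POSTN, which was low in both (0.101 against 0.509 CPM).

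Single genes separated the lines widely. ASTN1, a neuronal adhesion protein (chromosome 1, 176857321 to 177164712), was at 0.264 CPM in the parental line and 21.2 ± 1.3 in the deleted line (6.33 ± 0.16, adjusted p = 1.7e-15). Higher too were SYNDIG1 (4.66), the growth factor PTN (4.14; 0.929 against 16.4 CPM), the glutamate receptor gene GRIA2 (2.73; 12 against 79.6 CPM), TMEM132E (2.73), the matrix protease MMP2 (2.66; 2.60 against 16.5 CPM), SDSL (2.53), PPIAP46 (2.29), PDE11A-AS1 (2.14) and ACTG2 (2.03). AMBN was at 6.84 ± 0.414 CPM in the parental line and 0.032 ± 0.0378 in the deleted line. Lower as well were DHRS2 (−4.30 ± 0.39, adjusted p = 2.1e-07; 10 against 0.513 CPM), EDIL3 (−3.90), the growth factor BMP2 (−3.26; 23.5 against 2.46 CPM), TMEFF2 (−3.11), LAMC3 (−2.79), IFI16 (−2.41), NAP1L2 (−2.39), the haematopoietic signalling gene HCLS1 (−2.29; 10.5 against 2.13 CPM) and MOBP (−2.27; 52.3 against 10.9 CPM). In all, 4171 genes passed, 2015 higher and 2156 lower, 437 and 516 of them at least 2-fold. Of these, 48.3% were higher, and 52.6% with library size alone. The count was 2657 without parental replicate 3, 2593 without deleted-line replicate 1 and 2627 without deleted-line replicate 2.

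Whether the removal of doxycycline went with different changes in the deleted and the parental line was tested as the difference of both changes. The same single parental change, of unknown duration, was subtracted at each day, so these differences are not matched for time. At day 3, 8530 genes differed (4012 with a higher change in the deleted line, 4518 with a lower one). The share of higher ones was 47%, 42.7% with library size alone and 55.1% with the trend removed. At day 6, 2729 differed (1186 and 1543). That count was 1729 and 1645 without parental doxycycline replicates 2 and 3, 1625 without day 6 replicate 3 and 1725 without deleted-line doxycycline replicate 2. The share of higher ones was 43.5%, 50.5% with library size alone and 57.8% with the GC and length trend removed. At day 9, 11176 differed (5272 and 5904), with a share of higher ones of 47.2%, 39.6% with library size alone and 53.5% with the trend removed. SARS2 itself differed at day 3 (0.54 ± 0.14, adjusted p = 0.004; 0.37 and not passing with the trend removed) and at day 9 (0.94 ± 0.14, adjusted p = 1.1e-05; 0.60 with the trend removed), and gave 0.18 at day 6 (adjusted p = 0.41). DDIT3 changed less in the deleted line at day 3 (−1.13, adjusted p = 5.5e-05). ATF5 changed more in the deleted line at day 9 (0.60, adjusted p = 0.0058), a call lost with the trend removed (0.15). As a list, ATF4 targets changed less in the deleted than in the parental line at day 3 (median −0.24, camera adjusted p = 0.0044, adjusted p = 0.49 with an estimated correlation). They changed more at day 6 (0.20, adjusted p = 0.0094, adjusted p = 0.33 with an estimated correlation; 0.11 and not passing with the trend removed). At day 9 the list's difference between lines did not pass (0.25, adjusted p = 0.19).

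The changes at days 3 and 9 overlapped: 1228 genes were higher at both and 1265 lower at both, against 317 and 354 for independent lists, and 99.8% of the genes called at both had the same sign. Both use the same doxycycline libraries, which alone makes fold changes covary; across 12193 genes, Pearson's r of the fold changes was 0.75 (0.50 in simulations without effects) and the covariance 0.104 (0.0074 in simulations). Days 6 and 9 shared a sign in 29.1% of the genes called at both (r −0.19, simulated 0.49), and days 3 and 6 in 35.9% (r −0.01, simulated 0.49). The parental line without doxycycline shares no library with the deleted line's comparisons. Of genes called in it and at day 6, 93.9% had the same sign (1701 both higher against 637 for independent lists, 1602 both lower against 559; r 0.50). The share was 6.82% with day 3 (r −0.55) and 14.9% with day 9 (r −0.51). Of the 147 list calls over all comparisons, 5 held with an estimated correlation between genes: the ATF4 targets at day 6, at day 9, from day 3 to day 6, in the parental line and between lines.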

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

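Of the tests below, the level of ASTN1 in the parental libraries, the hypoxia list, NEAT1 and MALAT1, and the 3 tests on SARS2 were chosen only after their results were seen, and removing the GC and length trend was an alternative added after the data were examined.

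The next 3 paragraphs hold results where the response to removal of doxycycline differed between lines in a test of that difference. Values are the deleted line's log2 change minus the parental line's, and list values are medians. The parental change, of unknown duration, is the same at each day and can make up most of a value. All list calls among them were lost with an estimated correlation between genes, with a lowest adjusted p of 0.37 at day 3, 0.33 at day 6 and 0.25 at day 9.

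At day 3, 8530 genes differed. The change was higher in the deleted line for TCTA (1.79), GDAP1, a mitochondrial fission factor (2.16), the amino acid transporter SLC38A5 (1.60) and LRRN3 (2.54). It was lower for TXNIP (−4.72), its glucose-responsive relative ARRDC4 (−2.30), KLF10 (−2.15), the potassium channel KCNQ1 (−3.31) and YPEL1 (−2.34). Among lists, ribosome biogenesis (0.88), heat shock (0.68), DNA replication (0.35), nucleotide synthesis (0.30), mitochondrial DNA maintenance factors (0.28), mitochondrial ribosome (0.25), mitochondrial transfer RNA synthetases (0.21) and NRF2 targets (0.31) were higher. Hypoxia (−0.68), ATF4 targets (−0.24) and the cytosolic ribosome (−0.24, not called by fry, adjusted p = 0.1) were lower. The NRF2 call was lost without parental doxycycline replicate 1 (0.28) and with the GC and length trend removed (0.14). The mitochondrial transfer RNA synthetase call was lost with that trend removed (0.22, adjusted p = 0.052), but not where the replicate block was added.

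At day 6, 2729 genes differed (1625 to 3301 without 1 library). In the deleted line KLF10 was at 11.7 to 12.8 CPM, against 12 to 13.6 with doxycycline. Its value thus came mainly from the parental line, unlike that of BEST1. The change was higher in the deleted line for BEST1 (2.97), the chromatin ATPase MORC2 (1.09), UAP1L1 (0.89), LONP1, the main protease of the mitochondrial matrix (0.83), and TELO2 (1.04; 0.69 with the GC and length trend removed), and lower for TXNIP (−3.68), KLF10 (−1.75), ARRDC4 (−1.97), RBM12 (−1.02) and FDPS (−1.09). Epithelial markers (0.45), ribosome biogenesis (0.30), ATF4 targets (0.20) and DNA replication (0.09) were higher, of which fry did not call ribosome biogenesis (adjusted p = 0.14) and DNA replication (adjusted p = 0.079). Lower were cholesterol synthesis (−0.72), fatty acid synthesis (−0.50), metallothioneins (−0.58, lost without deleted-line doxycycline replicate 3, −0.43), the cytosolic ribosome (−0.35), complexes II to V (−0.33, and −0.17 with the trend removed), complex I (−0.26, then −0.15), hypoxia (−0.25, and −0.16 without day 6 replicate 1) and the tricarboxylic acid cycle (−0.10, lost with the trend removed but not with the block added, −0.09). The ATF4 call was lost with the trend removed (0.11). The DNA replication call was lost without the parental replicate 1 lacking doxycycline (0.06) or deleted-line doxycycline replicate 1 (0.06) or 2 (0.07).

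At day 9, 11176 genes differed. The change was higher in the deleted line for TCTA (2.18), TFPI2 (2.23), WDR77 (1.88), the nuclear importer IPO4 (2.27) and the vitamin transporter SLC5A6 (1.72), and lower for YPEL1 (−3.19), KCNQ1 (−4.12), HOTTIP (−2.11), DAZL (−2.39) and SERGEF (−1.68). Higher lists were metallothioneins (1.18), ribosome biogenesis (1.09), heat shock (0.98), DNA replication (0.64), NRF2 targets (0.58), mitochondrial DNA maintenance factors (0.47), mitochondrial ribosome (0.46, and 0.29 with the GC and length trend removed), the unfolded protein response (0.40), mitochondrial transfer RNA synthetases (0.32), glycolysis (0.30), mitochondrial chaperones (0.26) and nucleotide synthesis (0.25). Cholesterol synthesis (−0.98), fatty acid synthesis (−0.73), hypoxia (−0.72) and mitosis (−0.26) were lower. With the GC and length trend removed, calls were lost for NRF2 targets (0.29), the unfolded protein response (0.35), mitochondrial transfer RNA synthetases (0.26), glycolysis (0.26), mitochondrial chaperones (0.21) and fatty acid synthesis (−0.42). Leaving out 1 library ended the calls for fatty acid synthesis (parental replicate 2 or 3 lacking doxycycline, −0.74 and −0.72, day 9 replicate 2, −0.67, or deleted-line doxycycline replicate 1, −0.73), mitochondrial chaperones (parental replicate 2 lacking doxycycline, 0.29, parental doxycycline replicate 1, 0.24, day 9 replicate 3, 0.27, or deleted-line doxycycline replicate 1, 0.26), mitochondrial transfer RNA synthetases (day 9 replicate 3, 0.24) and mitosis (parental replicate 3 lacking doxycycline, −0.24, or day 9 replicate 1, −0.24, or 2, −0.19).

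ATF4 targets rose without doxycycline in the parental line, which carries no transgene, as in the deleted line. A bias with GC content and gene length is argued against as the whole cause, since the list passed with that trend removed (camera adjusted p = 2.8e-11, median 0.61). Cells of the deleted line in those libraries are argued against by ASTN1, at most 0.3 CPM there. A culture state at harvest that differed between the parental groups, such as density, glucose or oxygen, may contribute, since the hypoxia list rose as well (adjusted p = 1.5e-05, adjusted p = 0.11 with an estimated correlation). An effect of doxycycline itself, and an exchange of labels between both parental groups, for which no gene here marks the drug, stay open as untested.

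Fold changes followed the genomic span of genes, with longer genes higher at day 6 and lower at day 9. Sources were tested only for the change from day 6 to day 9. There GC content is argued against as the whole source, since the rank correlation with span, given GC content, was −0.40 across 11598 genes. Exonic length is argued against in the same way (−0.29 given exonic length), and library depth by a prediction of −6.64% ± 3.82 (SE) of the difference between the longest and the shortest genes. NEAT1, an RNA retained in the nucleus, moved with the pattern (1.25 at day 6, −1.24 at day 9 and 1.89 in the parental line), while MALAT1, another, gave 0.12 and −0.08 at days 6 and 9 and 0.60 in the parental line. RNA quality, the share of nuclear or unspliced RNA and a change in transcription of long genes stay open, and each could follow the labelled day or the day of harvest.

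Counts assigned to SARS2 did not fall after removal of doxycycline. ASTN1, picked on the doxycycline groups, was at 12.9 CPM or more in the 12 deleted-line libraries and at most 0.3 in the 6 parental ones. This argues against an exchange of the other groups, unless whole lines were swapped. The day 9 rise of SARS2 (0.79 ± 0.10, SE) would go against mainly transgene reads only if the transgene was off and the labels hold. No value here shows that, so that source stays open. Log2 changes of SARS2 minus MRPS12 were 0.67 ± 0.17 (SE) at day 6, 0.41 ± 0.17 at day 9 and, within 2 SE, 0.19 ± 0.17 at day 3. With the GC and length trend left in and an equal response of both untested, a change of their shared promoter stays open. RNA of the deleted locus that is still counted, an exchange among the deleted line's groups, and a transgene that stayed on remain open as untested, and the last could leave SARS2 protein in place.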

How the results depend on the processing

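All alternatives were planned except removing the GC and length trend, chosen after the data were examined.

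Of 188 recomputed counts of genes, 168 stayed within 1.5 times the reported count and 20 moved. Of the single genes and lists, 7537 recomputed values kept direction and side of the threshold, 454 lost the call, 25 gained one and 37 reversed. Of these 37, 6 had passed the test, all with the trend removed, and 31 had passed it neither way, 25 of them under alternatives chosen before. With an adjusted p under 0.01, counts were 1060 at day 3, 3519 at day 6, 2172 between lines and 952 for the difference between lines at day 6. With only the groups compared in the fit, counts were 6536 at day 3 and 7336 between lines; the cause was not tested. Leaving out 1 library, which leaves fewer samples, gave 1088 to 2564 genes at day 3, 3834 to 5855 at day 6, 8522 to 10137 at day 9, 7586 to 8721 from day 3 to 6, 11651 to 12584 from day 6 to 9, 6916 to 8214 in the parental line, 2593 to 3846 between lines, and 7378 to 8504, 1625 to 3301 and 10342 to 11360 for the differences between lines at days 3, 6 and 9. With the trend removed, 8238 genes passed from day 6 to day 9 (8211 with the block), of the 11598 tested, which are fewer. The 6 reversed values that had passed were ATF4 at day 9, from 0.17 to −0.03 (−0.04 with the block), and the cytosolic ribosome's median. That went from −0.15 to 0.06 (0.06) between days 3 and 6 and from 0.28 to −0.11 (−0.11) between days 6 and 9. The cause was not tested. Of values that did not pass, ATF4 went with the trend removed, with or without the block, from −0.06 to 0.13 between days 3 and 6 (0.01 with library size alone), and in the difference between lines from 0.08 to −0.19 at day 3 and from 0.03 to −0.06 at day 6. At day 9 that difference went from 0 to 0.01 with DESeq2 size factors, with the DESeq2 test and with no low-count filter. With the trend removed, calls were gained there for ATF4 (−0.47, adjusted p = 0.0011), DDIT3 (−0.21 to −0.53) and SIRT2 (−0.12 to −0.35). ATF4 from day 6 to 9 (−0.03) gained one with the trend removed (−0.42, adjusted p = 0.00014) and with library size alone (−0.16, adjusted p = 0.0089). Leaving out 1 library gave −1.64 to 0.06 for FBXO17 at day 3, −0.01 to 0.06 for SARS2 at day 6 and −0.33 to 0.08 for MALAT1 at day 9. For CCER2 it gave −0.56 to 0.01 at day 6, −0.23 to 0.11 at day 9, −0.16 to 0.40 from day 3 to 6 and −0.10 to 0.48 from day 6 to 9. For ATF4 leaving out 1 library gave −0.08 to 0.01 from day 6 to 9 and, in the difference between lines, 0 to 0.09 at day 6 and −0.05 to 0.05 at day 9. SIRT2 had −0.07 to 0.03 in that difference at day 3.

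Of the 147 list calls, 142 were lost with an estimated correlation, 17 with fry and 38 with the trend removed. Of the named genes' calls, 12 were lost with the trend removed, 13 with only the groups compared, 9 with no low-count filter, 4 with library size alone, 3 with limma-voom, 1 with the DESeq2 test and 1 with DESeq2 size factors. The DESeq2 test called 3784, 6711 and 10425 genes at days 3, 6 and 9. Library size alone shifted the median of all genes by −0.127 from day 6 to day 9 and −0.104 in the difference between lines at day 9, so changes there are relative to that. Leaving out the mitochondrial chromosome changed nothing, since its counts are 0.

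With the replicate number as a block, 2674, 5834 and 9888 genes passed at days 3, 6 and 9, 9067 and 12565 between days, 8421 in the parental line, 4021 between lines, and 8365, 2567 and 11049 for the differences between lines. The block ended 4 calls of named genes (EDEM1, TM7SF2 and MRPS12 at day 9, RNA45SN2 in the parental line) and none of the 147 list calls. The numbers do not pair the libraries: residuals of same-numbered libraries correlated between −0.30 and 0.25, with 10 of 45 pairs over 0.1, and 5 of 18 libraries correlated best with their own number.

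In the self-test, 54% of genes changed 1.5-fold were called at day 9, and 34% in the difference between lines.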

Other observations

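The reading of LOC124900647 was chosen after its values were seen.

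The lists of cytosolic and of mitochondrial transfer RNA synthetase genes were not tested against each other. In the libraries labelled day 9, of 20 cytosolic synthetase genes, 11 rose and 9 did not pass (11 higher and 1 lower adjusted over the list alone). Cytosolic synthetases had a median of 0.28 (camera adjusted p = 0.00054, adjusted p = 0.63 with an estimated correlation). Among them were WARS1 (0.97 ± 0.07, SE; 143 to 281 CPM), CARS1 (0.53), MARS1 (0.60; 270 to 410 CPM) and FARSA (0.83). Of 20 mitochondrial ones, 8 rose, 5 fell and 7 did not pass (8 and 5 adjusted over the list alone). Mitochondrial synthetases had a median of 0.08 (camera adjusted p = 0.42). SARS2 was among those that rose. AARS2 (0.65, adjusted p = 1.5e-05; 46.1 to 72.6 CPM), CARS2 (0.43) and YARS2 (0.38, and 0.22 with the GC and length trend removed) rose, while RARS2 (−0.41, adjusted p = 0.00012; 70.3 to 53 CPM) and IARS2 (−0.25, adjusted p = 0.0033) fell. NARS2 (−0.41) and FARS2 (−0.49) fell as well. With the GC and length trend removed FARS2 lost its call (−0.04), and NARS2 (−0.21) kept it, but lost it where the replicate block was added (−0.21). At day 6, 1 of the mitochondrial synthetases rose and 8 fell (2 and 10 adjusted over the list alone). Mitochondrial synthetases had a median of −0.15 (camera adjusted p = 0.00093, adjusted p = 0.17 with an estimated correlation). In the parental line without doxycycline 1 rose and 11 fell (1 and 11 adjusted over the list alone). These synthetases had a median of −0.24 (camera adjusted p = 0.00051, adjusted p = 0.38 with an estimated correlation).

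In the parental line without doxycycline, 23 of 34 DNA replication genes fell and 1 rose (24 and 1 adjusted over the list alone). DNA replication genes had a median of −0.23 (camera adjusted p = 1.5e-07, adjusted p = 0.22 with an estimated correlation). Among them UHRF1, which maintains DNA methylation at replication (−1.02, adjusted p = 3.1e-07; 268 to 132 CPM), FEN1 (−0.65), GINS4 (−0.64) and MCM2 (−0.53; 500 to 347 CPM) fell, and the clamp loader RFC4 rose (0.22, adjusted p = 0.0098; 88.9 to 104 CPM). Nucleotide synthesis genes fell in 11 of 17 cases there (median −0.24, camera adjusted p = 7.6e-05, adjusted p = 0.47 with an estimated correlation), and factors for mitochondrial DNA maintenance in 15 of 31 (median −0.24, camera adjusted p = 0.0048, adjusted p = 0.49 with an estimated correlation). Between lines with doxycycline, 13 of 30 lysosome and autophagy genes were lower in the deleted line and 1 higher (14 and 2 adjusted over the list alone). Lysosome genes had a median of −0.20 (camera adjusted p = 0.00015, adjusted p = 0.2 with an estimated correlation). Among them were FLCN and FNIP2, partners in signalling of nutrients at the lysosome (−0.90 and −0.53), LAMP1 (−0.35; 161 to 126 CPM) and NEU1 (−0.56). WIPI1, higher at 0.41 (adjusted p = 0.014), lost its call without parental doxycycline replicate 2 (0.39) or 3 (0.39) or deleted-line replicate 1 (0.36).

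Other lists gave the following. Mitochondrial chaperones and proteases were lower in the deleted line with doxycycline in 6 of 18 cases (median −0.12, camera adjusted p = 0.0037, adjusted p = 0.36 with an estimated correlation). NRF2 targets rose at day 9 in 11 of 18 cases and fell in 2 (median 0.32, camera adjusted p = 0.028, adjusted p = 0.61 with an estimated correlation), a call lost with the GC and length trend removed (0.19). Tricarboxylic acid cycle genes fell at day 6 in 8 of 26 cases and rose in 3 (median −0.11, camera adjusted p = 0.024, adjusted p = 0.36 with an estimated correlation), a call lost with that trend removed (−0.05). Fatty acid oxidation genes fell at day 3 in 2 of 19 cases (median −0.11, camera adjusted p = 0.019, adjusted p = 0.68 with an estimated correlation). That call was lost without day 3 replicate 1 (−0.12) or deleted-line doxycycline replicate 3 (−0.10), and with the trend removed (−0.06). Replication-dependent histones fell in 9 of 26 cases and rose in 1 in the parental line (median −1.02, camera adjusted p = 0.046, adjusted p = 0.92 with an estimated correlation), a call lost without replicate 1 (−0.95) or 2 (−1.17) lacking doxycycline or doxycycline replicate 3 (−0.42), and with fry (adjusted p = 0.27). Mitosis genes fell at day 9 in 14 of 34 cases and rose in 4, without passing as a list (median −0.14, camera adjusted p = 0.072). The 5 lists called in none of the 10 comparisons were, with their values at day 9, interferon response (8 of 29 rose, 5 fell, median 0.04, adjusted p = 0.41), NF-kB targets (4 of 12 rose, median 0.20, adjusted p = 0.28) and p53 targets (6 of 18 rose, 3 fell, median 0.09, adjusted p = 0.34). The others were haematopoietic markers (4 of 11 rose, 1 fell, median 0.35, adjusted p = 0.52), and serine, glycine, one-carbon and proline synthesis (10 of 20 rose, 2 fell, median 0.19, adjusted p = 0.08). Medians and tests differed in sign in 16 list tests, of which 0 were called, among them mesenchymal markers at day 9 (median 0.05, tested downward, adjusted p = 0.66) and lysosome genes in the parental line (median 0.10, tested downward, adjusted p = 0.83).

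CPM of the 3 libraries of each group did not overlap for 42.1%, 47.2% and 50.9% of genes at days 3, 6 and 9, where chance gives 10%. For the comparisons of 3 libraries with 3, the 10 splits of the libraries are too few for a share under 0.05. In fits of only the groups compared, 1 split, the real one, gave the most genes. It gave 10831 from day 3 to 6, 11050 from day 6 to 9, 8414 in the parental line and the counts given above for the rest, against at most 0 in the other splits. For the differences between lines, 50 of 200 splits were drawn. At day 3, 1 of 50, the real one, gave as many genes (9628 against at most 7160), and at day 9 1 of 50 (10346 against at most 4555). At day 6, 3 of 50, the real one included, gave as many (3309, with up to 5841 in another split). At each day the splits with many calls kept the groups of 1 line or of both whole and so tested those lines' own changes, while the splits that mixed the libraries of both lines called at most 0, 0 and 1 genes. The count of splits therefore does not decide, at any of these days, whether chance is excluded.

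LOC124900647 (chromosome 4, 1113639 to 1203194) held 46118 counts in replicate 3 of the deleted line with doxycycline, and 4 and 154 in the other replicates of that group. It held 1179 in replicate 2 of the parental line without doxycycline.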
